A study of Mus musculus with 12 samples.

How the data were processed

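The samples were 12 arrays of the mouse lung tumour line A2C12, per the labels in 4 groups of 3 biological replicates (SP or non-SP, with or without anti-EpCAM antibody). Per the labels' protocols, cells received the antibody at 100 µg/ml for 48 h or none, were stained with Hoechst dye at 5 µg/ml for 90 min, with reserpine at 50 µmol/l as the control for the SP gate, and were sorted by flow cytometry. Per the same protocols 200 ng of total RNA were amplified and labelled with biotin for the Affymetrix mouse genome array. The deposited values are on the log2 scale, and per the submitters' processing notes the authors summarised them by RMA. The software and its version are not given in the sources used here, and whether another scaling followed is not given either, since array medians ran from 5.72 to 6.06. Only the processed table was used, and probe-level files were not used here.

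The table held 45101 probe sets, of which 34958 had 1 gene symbol, 932 had several and 9211 had none in the platform annotation, dated 2016. Among probe sets with 1 symbol, that with the highest mean over all 12 arrays stood for its gene, which gave 18194 genes, and 1568 of these probe sets carry an x_at or s_at name and can take up signal from related transcripts. No filter on level was applied. The 64 control probe sets served only to look at RNA quality. Epcam was read from such an x_at probe set, and its other probe set had a mean of 4.61. That probe set gave log2 differences of 0.11 and -0.13 between fractions and of -0.04 and -0.28 between treatments. Abcb1a and Abcb1b also had another probe set, with means of 6.88 and 4.33. Cd44 had others with means of 11.6, 9.60 and 3.54, and Cd24a with means of 12.6 and 11.9. Their differences are given with each comparison, in this order.

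Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without trend, group means over all 12 arrays, 8 residual degrees of freedom, no block), two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 5 contrasts were SP against non-SP in untreated and in treated cells, anti-EpCAM against untreated in non-SP and in SP cells, and the interaction. The median 95% interval reached 0.46 log2 units to either side (1.38-fold), and 0.65 (1.57-fold) for the interaction. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists within a contrast, and beside it with an estimated correlation and with fry, which asks whether the genes of a list move one way and compares them with no other genes. Neither of these called a list in any contrast, with a lowest adjusted p of 0.80 with an estimated correlation, 0.436 for fry and 0.938 for its mixed form. Of 427 list genes, 405 were measured, 4 of them through an older symbol. Figures and label handling used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

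The contrasts, lists, threshold and named genes were chosen before the data were examined. Named are, per contrast, the genes past the threshold or, as here with none, the 3 highest and 3 lowest by moderated t without clone and predicted gene names, up to 4 genes with the lowest p of each list discussed, and a fixed set of 10 genes. Of that set, 2 had no probe set with a gene name of their own and were not analysed here.

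Replicate numbers were checked as possible pairs. The deviations of the SP and non-SP array of one number from their group means correlated across genes at 0.66, 0.84 and 0.55 in untreated and at 0.75, 0.62 and 0.56 in treated cells, while those of untreated and treated arrays of one number were all negative, from -0.38 to -0.00541. The SP and non-SP arrays of one number and treatment are therefore called a culture here, although the labels do not state it. By the correlation of whole arrays 11 of 12 matched the other array of their culture best. The exception was SP anti-EpCAM replicate 2, whose correlation with its partner, 0.987, was the lowest within a culture and whose best match was SP untreated replicate 1. The median SD over genes was 0.15 within a culture and 0.27 within a group. The planned fit has no culture term, and a culture block was added as an alternative for the fraction contrasts and the interaction, with a median interval reaching 0.27 and 0.38 log2 units to either side. Standard errors and intervals of single genes are from the planned fit. In the fraction contrasts and the interaction they therefore include the spread between cultures.

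The procedure was tested on simulated data with independent arrays, thus without the correlation within cultures, in 4 comparisons with 100 changed genes at each fold. Of genes changed 2-fold it recovered 60, 71, 57 and 65%, and of genes changed 4-fold 100, 99, 99 and 98%. The false calls numbered 4, 9, 13 and 11. Of 20 lists, the 1 shifted by 0.5 was called in each of the 4 comparisons, and 1 of the unshifted lists was called in the first. The simulated genes were independent of each other as well, while the estimated correlation within the real lists reached 0.83. The simulation thus does not show how often lists of correlated genes are called falsely.

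Alternatives were fits on only the groups compared, a block for the replicate number, the mean of a gene's probe sets, genes with a mean of 5 or more, the upper 50% by mean, eBayes with trend and robust settings, array weights, arrays centred on their median, a further quantile normalization, a stricter adjusted p of 0.01, and leaving out each array. Gene counts were recomputed under each. List calls were recomputed with the replicate block, the mean of probe sets, genes with a mean of 5 or more, array weights and each array left out. Correlations of effects were recomputed with the mean of probe sets, genes with a mean of 5 or more, the upper 50% and each array left out. Neither was recomputed with centred or further normalised arrays. The splits of the samples into other groups of the same size were also fitted, and all results rest on the number of arrays, which limits their precision.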

Results

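Transcript levels were measured on Affymetrix mouse genome expression arrays in A2C12, a lung tumour cell line from mice carrying c-myc and c-raf transgenes on a C57BL/6 background. Cells were sorted into a side population (SP), which keeps little of the DNA dye Hoechst because membrane pumps remove it, and the remaining non-SP cells. EpCAM is an adhesion protein on the surface of epithelial cells, and part of the cells received an anti-EpCAM antibody at 100 µg/ml for 48 h before sorting. The 4 groups were non-SP untreated, SP untreated, non-SP anti-EpCAM and SP anti-EpCAM, each with 3 biological replicates, giving 12 arrays. The table held 45101 probe sets without missing values, and 18194 genes were tested. Array medians lay between 5.72 and 6.06 log2 units, and single values between 2.28 and 14.7. The number of arrays limits the precision of every value given here.

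The first comparison asks how the transcripts of the dye-excluding cells differ from those of the other cells in untreated culture. Abcg2, which encodes the pump most often tied to the SP phenotype, was at 8.54 ± 0.04 (SD, n = 3) in non-SP cells and 8.60 ± 0.26 (SD, n = 3) in SP cells. Its log2 difference was 0.06, with a 95% interval from -0.28 to 0.40. Abcb1a and Abcb1b, which encode the P-glycoprotein drug pumps, differed by 0.20 ± 0.38 (SE) and 0.04 ± 0.43 (SE). Epcam itself was at 8.22 ± 0.19 (SD, n = 3) in non-SP and 8.16 ± 0.22 (SD, n = 3) in SP cells, a log2 difference of -0.06 ± 0.18 (SE). The progenitor markers Prom1, Cd44 and Cd24a differed by 0.03, 0.01 and -0.02, and the transgene-related Myc by -0.09. Each of these differences was smaller than its standard error in the fit without a culture term, and none passed the threshold. With each culture as a block the median interval was narrower, at 0.27 against 0.46 log2 units to either side. Errors of single genes from that fit are not given here. Read from their other probe sets, Abcb1a differed by 0.05 and Abcb1b by -0.01. Epcam differed by 0.11 in its other probe set, which had a mean of only 4.61. Cd44 differed by -0.00, 0.15 and -0.14 in its others, and Cd24a by -0.09 and 0.02.

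Genes of late cell division were lower in untreated SP cells by the list test. Of the 19 measured G2/M genes, all 19 lay below the median change of all genes, and their median log2 difference was -0.23. Ube2c, which targets mitotic cyclins for destruction, differed by -0.37 ± 0.37 (SE), and Plk1, a kinase of mitotic entry, by -0.31 ± 0.33 (SE). The spindle genes Nusap1 and Cenpe differed by -0.36 and -0.24. The list was called by camera at an adjusted p = 1.9e-08, against an adjusted p = 0.80 with an estimated correlation between its genes. Its difference between the SP and non-SP array of one replicate number was -0.66, -0.25 and 0.17 in the 3 untreated cultures, and without SP untreated replicate 1 the adjusted p was 0.838. The DNA replication genes of G1/S did not pass, with Uhrf1 at -0.22, Gins2 at -0.14, a list median of -0.02 and an adjusted p of 0.356.

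Genes of the unfolded protein and amino acid response were higher in untreated SP cells by the same test. Of 18 measured genes, 14 lay above the median of all genes, and the list median was 0.13. Trib3, a pseudokinase induced by endoplasmic reticulum stress, differed by 0.40 ± 0.32 (SE), and Asns, which makes asparagine, by 0.27 ± 0.25 (SE). Ddit3, a stress transcription factor, differed by 0.24 and Herpud1, which serves protein degradation, by 0.16. All 4 genes were higher in the SP array of 3 of 3 cultures. They were picked for the lowest p in this contrast, so this is no separate support. The camera test gave an adjusted p = 0.0072, and an adjusted p = 0.80 with an estimated correlation. The call also ended without SP untreated replicate 1 (0.907), without non-SP untreated replicate 2 (0.0741) and without non-SP untreated replicate 3 (0.335).

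The 15 measured ABC transporter genes had a median log2 difference of -0.06, with 6 above and 9 below the median of all genes (camera adjusted p = 0.454). Within them Abca5 differed by 0.22 and Abcc3 by -0.20. The 21 stem and progenitor markers had a median of 0.01, with Nanog at -0.27, Aldh3a1 at -0.34 and Itga6 at 0.17 (camera adjusted p = 0.654). The highest moderated t values, none past the threshold, belonged to the calcium channel gene Cacna1h at 0.44, the olfactory receptor gene Olfr74 at 0.38 and the adhesion gene Nrcam at 0.43. The lowest belonged to Strip2 at -0.52, the chaperone gene Dnajb5 at -0.37 and the pheromone receptor gene Vmn1r40 at -0.32. Most of them had low array levels, with means of 3.46 for Olfr74, 4.34 for Nrcam, 3.33 for Strip2 and 3.52 for Vmn1r40. Cacna1h and Dnajb5 had means of 4.99 and 6.38. With limma, 0 genes were higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 4 genes, 3 higher and 1 lower. Independent arrays would give 910 by chance, but the SP and non-SP array of one culture resemble each other, so this number does not apply to the fraction comparisons. With each culture as a block the counts were again 0, with 305 genes at an unadjusted p under 0.05. The 95% interval of 17557 genes (96.5%) lay inside a 2-fold change in either direction. The 3 SP arrays lay all above the 3 non-SP arrays for 226 genes and all below for 206, which is 2.37% of genes. Chance gives 10% for independent arrays and, for the same reason, not for these. Over the 28 lists, 0 genes passed over all genes and 0 passed when adjusted over the list alone. The 26 lists not called had adjusted p from 0.166 to 0.969, and in 5 of the 28 the median, mean and test differed in sign.

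The second comparison asks the same of cells that had received the antibody. Abcg2 was at 8.18 ± 0.11 (SD, n = 3) in non-SP cells and 8.27 ± 0.07 (SD, n = 3) in SP cells, a log2 difference of 0.08 with a 95% interval from -0.26 to 0.42. That difference changed sign, to -0.00, when the arrays were quantile normalised again. Abcb1b differed by 0.47 ± 0.43 (SE) and Abcb1a by 0.36 ± 0.38 (SE), with replicate SDs between 0.66 and 0.98 in the 4 groups of values behind them. Epcam was at 8.08 ± 0.18 (SD, n = 3) in non-SP and 7.99 ± 0.21 (SD, n = 3) in SP cells. Prom1 differed by -0.40 ± 0.29 (SE), Cd44 and Cd24a by -0.02 each (0.03 each when the arrays were centred on their medians), and Myc by -0.11. None of these passed the threshold. Other probe sets gave 0.44 for Abcb1a, -0.04 for Abcb1b and -0.13 for Epcam. For Cd44 they gave 0.23, 0.04 and 0.15, and for Cd24a 0.01 and 0.22, so the values near 0 of Cd44 and Cd24a depended on the probe set.

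G2/M genes were again lower in SP cells by camera, with 19 of 19 genes below the median of all genes and a median log2 difference of -0.29. Ube2c differed by -0.46 ± 0.37 (SE), Ccna2, the S and G2 phase cyclin, by -0.41 ± 0.31 (SE), the checkpoint kinase gene Ttk by -0.35 and Cdk1, the main mitotic kinase, by -0.34. The adjusted p was 0.0031, and the adjusted p was 0.89 with an estimated correlation. The list difference was 0.20, -0.91 and -0.00 in the 3 treated cultures, so the treated culture numbered 2 supplied it. The 2 arrays of that culture had the highest actin 3' minus 5' signals, at 0.895 and 1.03 against at most 0.733 elsewhere, and the lowest mean correlations with other arrays, at 0.982 and 0.985. Without SP anti-EpCAM replicate 2 the list was higher rather than lower at an adjusted p of 0.0526, and without non-SP anti-EpCAM replicate 3 the adjusted p was 0.431. Over all 6 cultures the differences had a mean of -0.24 ± 0.46 (SD, n = 6), with 4 lower, 1 of them close to 0, and 2 higher. A two-sided exact sign-flip permutation test over the 6 cultures gave p = 0.281 (0.909 adjusted over the 28 lists), where the smallest possible is 0.0312. With arrays centred on their medians 3 cultures were lower and 3 higher, and the exact test gave p = 0.312 (1 adjusted).

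Ribosome biogenesis genes came next, with 14 of 16 above the median of all genes, a median of 0.12 and a camera adjusted p of 0.0813. Among them Wdr43 differed by 0.33 ± 0.26 (SE) and the nucleolar genes Npm1 and Ncl by 0.18 and 0.16. The list difference was -0.03, 0.54 and -0.05 in the 3 treated cultures, so it too lay in culture 2. The unfolded protein list, called in untreated cells, had a median of 0.03 and an adjusted p of 0.36 in treated cells. ABC transporter genes had a median of 0.02 (9 higher, 6 lower than the median of all genes, adjusted p = 0.544), and stem and progenitor markers -0.05 (adjusted p = 0.488). The highest moderated t values, none past the threshold, were those of the sugar phosphate gene Pgm2l1 at 0.56, Zfp995 at 0.74 and the poly(A) regulator gene Pan3 at 0.53. The lowest were those of Trim75 at -0.69, BC049762 at -0.44 and the peptide hormone gene Edn3 at -0.59. The limma counts were 0 higher and 0 lower, with 127 genes at an unadjusted p under 0.05 (54 higher, 73 lower). Centring each array turned that split to 93 higher and 53 lower. With each culture as a block 0 genes passed and 1311 had an unadjusted p under 0.05. The 95% interval lay inside a 2-fold change for 16988 genes (93.4%). Arrays did not overlap for 104 genes higher and 323 lower in SP cells (2.35%, where independent arrays would give 10% by chance). Of the genes in the 28 lists, 0 passed over all genes and 0 when adjusted over the list alone, and in 3 lists the median, mean and test differed in sign.

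**Figure D1:**
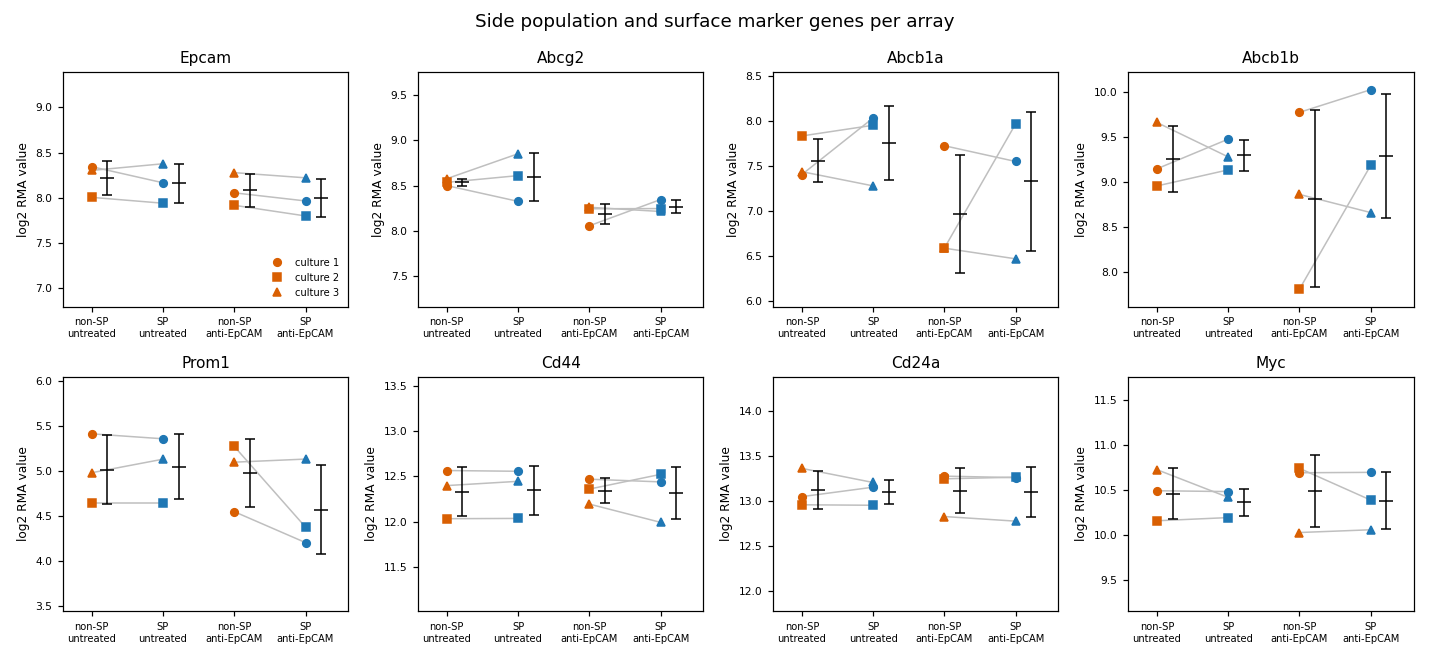
Log2 level of 8 genes fixed in advance on the vertical axis, with points for single arrays of the 4 groups, grey lines joining the SP and non-SP array of one culture, and bars for the mean and SD (n = 3). Abcg2 lies at 8.54 and 8.60 in untreated and at 8.18 and 8.27 in treated non-SP and SP cells, and no difference passed the threshold.

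The third comparison asks what the antibody did to the transcripts of non-SP cells. The median change of all genes was -0.10 log2 units, so changes are also given relative to it. Abcg2 was at 8.54 ± 0.04 (SD, n = 3) without and 8.18 ± 0.11 (SD, n = 3) with the antibody, a change of -0.35 ± 0.16 (SE), or -0.25 relative to all genes. It was -0.21 with centred arrays and -0.17 after a further quantile normalization. Its adjusted p in limma was 0.988. The change of Epcam, the antibody's target, was -0.13 ± 0.18 (SE), or -0.03 relative to all genes, and it turned to 0.01 with centred arrays and to 0.05 after a further quantile normalization. Abcb1a changed by -0.59 ± 0.38 (SE), Abcb1b by -0.44 ± 0.43 (SE), Prom1 by -0.04, Cd44 by 0.01, Cd24a by -0.01 and Myc by 0.03, and none passed the threshold. With centred arrays Prom1 and Cd24a turned to 0.10 and 0.14, and Abcb1a, Abcb1b, Cd44 and Myc stood at -0.45, -0.30, 0.15 and 0.17. After a further quantile normalization these 6 genes stood at 0.07, 0.08, -0.43, -0.28, 0.09 and 0.14, in the same order. In their other probe sets, with the values as deposited, Abcb1a changed by -0.47, Abcb1b by 0.13 and Epcam by -0.04. Cd44 changed by -0.07, 0.05 and -0.43 there, and Cd24a by -0.13 and -0.15.

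Dll4, which encodes a Notch ligand, changed by 0.78 ± 0.21 (SE) in non-SP cells and Lfng, which modifies Notch receptors, by -0.60 ± 0.17 (SE), or 0.88 and -0.50 relative to all genes. These were the 2 genes in the 28 lists that passed when adjusted over the list alone, with a lowest p of 0.0261, while 0 of the list genes passed over all genes. The Notch list as a whole did not pass, with 9 genes above and 7 below the median of all genes (camera adjusted p = 0.732). Other genes with the highest moderated t values were Nnat, an imprinted membrane protein gene, at 0.69 ± 0.17 (SE) and Ina, a neurofilament gene, at 0.70. The lowest t values were those of the mitochondrial enzyme gene Sugct at -0.84, Ncf1, which encodes a part of the phagocyte oxidase, at -0.73 and Ankrd29 at -0.88. Most of these genes had low array levels, such as a mean of 4.02 for Nnat and 4.88 for Ncf1. Zeb2, a repressor of epithelial genes, changed by -0.89 ± 0.26 (SE), and Tgfbi by -0.81 ± 0.37 (SE), in a mesenchymal list that did not pass (adjusted p = 0.657).

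With limma, 0 genes passed in either direction in non-SP cells, and the lowest adjusted p was 0.988. At an unadjusted p under 0.05 there were 585 genes, 94 higher and 491 lower, against 910 by chance. That split turned with the scaling, to 560 higher and 88 lower when each array was centred on its median and to 416 and 169 when the arrays were quantile normalised again. The treated arrays lay all above the untreated for 216 genes and all below for 1204 (7.80%, chance 10%). The 95% interval lay inside a 2-fold change for 16432 genes (90.3%). No list was called, with adjusted p from 0.657 to 0.924 over 28 lists. Among them were ABC transporter genes at a median of -0.08 relative to all genes (adjusted p = 0.674) and stem and progenitor markers at 0.09 (adjusted p = 0.657). In 7 lists the median, mean and test differed in sign.

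The fourth comparison asks the same of SP cells, where the median change of all genes was -0.12. Abcg2 was at 8.60 ± 0.26 (SD, n = 3) without and 8.27 ± 0.07 (SD, n = 3) with the antibody, a change of -0.33 ± 0.16 (SE), or -0.21 relative to all genes. With centred arrays it was -0.13, and after a further quantile normalization -0.25. Epcam changed by -0.17 ± 0.18 (SE), or -0.05 relative to all genes, and stood at 0.03 with centred arrays and at -0.08 after a further quantile normalization. Among the other genes fixed in advance, Prom1 changed by -0.47 ± 0.29 (SE), Abcb1a by -0.42 ± 0.38 (SE), Abcb1b by -0.01, Cd44 by -0.03, Cd24a by -0.00 and Myc by 0.02. With centred arrays Abcb1b, Cd44 and Cd24a turned to 0.19, 0.17 and 0.19, and Prom1, Abcb1a and Myc stood at -0.28, -0.23 and 0.21. After a further quantile normalization these 6 genes stood at 0.09, 0.03, 0.06, -0.26, -0.33 and 0.09, in the same order. None of these genes passed the threshold. The other probe set of Abcb1a gave only -0.08 with the values as deposited, that of Abcb1b gave 0.10 and that of Epcam gave -0.28. Those of Cd44 gave 0.17, -0.06 and -0.14, and those of Cd24a gave -0.02 and 0.06.

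Lef1, a transcription factor of the Wnt pathway that also acts with the cleaved tail of EpCAM, changed by -0.64 ± 0.17 (SE) in SP cells, or -0.52 relative to all genes. Fcer1g, an antibody receptor subunit gene, changed by -0.66 ± 0.19 (SE), or -0.54 relative to all genes. Lef1, in the EpCAM and in the Wnt list, and Fcer1g, in the immune list, gave the 3 entries that passed when adjusted over the list alone (lowest p 0.0361), and 0 list genes passed over all genes. In non-SP cells Lef1 changed by -0.50 ± 0.17 (SE) and Fcer1g by -0.29 ± 0.19 (SE). Nnat and Ncf1 stood among the extreme t values in both fractions, whose arrays share cultures, at 0.71 ± 0.17 (SE) and -0.90 ± 0.18 (SE) in SP cells. The others were Tcf24 at 0.50, the transporter gene Slc13a3 at 0.59, the milk protein gene Csn2 at -0.83 and the leukocyte integrin gene Itgal at -0.72. The lowest adjusted p of any gene was 0.776.

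Relative to all genes, 4 lists were higher in treated SP cells by camera. In the MAPK output list all 15 genes lay above the median of all genes, by a median of 0.13, with Phlda1 at 0.46, the feedback inhibitor genes Spred2 and Spry2 at 0.34 and 0.33 and the transcription factor gene Fosl1 at 0.30 (adjusted p = 0.0015, and 0.85 with an estimated correlation). The xenobiotic and oxidative stress list had 13 of 16 above, by a median of 0.21, with the detoxifying enzyme genes Cyp1a1 at 0.74 and Gstm1 at 0.33, the glutathione synthesis gene Gclm at 0.40 and Gsr at -0.09 (adjusted p = 0.0015, and 0.85 with an estimated correlation). The p53 target list had 16 of 19 above, by a median of 0.14, with the death genes Pmaip1 at 0.59, Perp at 0.46 and Bbc3 at -0.05 (adjusted p = 0.020, and 0.85 with an estimated correlation). Ribosome biogenesis genes had 15 of 16 above, by a median of 0.13, with Nop58 at 0.42 and Rrp12 at 0.29 (adjusted p = 0.020, and 0.85 with an estimated correlation). Their medians before subtracting the shift of all genes were 0.01, 0.09, 0.02 and 0.01. Without SP untreated replicate 2 the lowest of the 4 adjusted p was 0.126, and without SP anti-EpCAM replicate 1 it was 0.0525, so none of the 4 calls held without either array. The p53 and ribosome biogenesis calls also ended without SP anti-EpCAM replicate 2, at 0.238 and 0.595. That array had the highest actin 3' minus 5' signal of all, 1.03, and the highest mean of both lists among treated SP arrays, 0.23 and 0.31, while the ribosome biogenesis call ended without SP untreated replicate 3 as well (0.160).

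The ABC transporter list had a median of 0.09 relative to all genes in treated SP cells (10 higher, 5 lower, adjusted p = 0.725), with Abca2 at -0.30 and Abca5 at -0.29 relative to all genes. Stem and progenitor markers stood at 0.08 (adjusted p = 0.406). With limma, 0 genes were higher and 0 lower, and 835 had an unadjusted p under 0.05, 20 higher and 815 lower. That split was 284 higher and 174 lower after centring and 168 and 233 after a further quantile normalization. The arrays did not overlap for 79 genes higher and 1462 lower (8.47%, chance 10%), and the 95% interval of 16470 genes (90.5%) lay inside a 2-fold change. The 24 lists not called had adjusted p from 0.147 to 0.811, and in 4 lists the median, mean and test differed in sign.

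**Figure D2:**
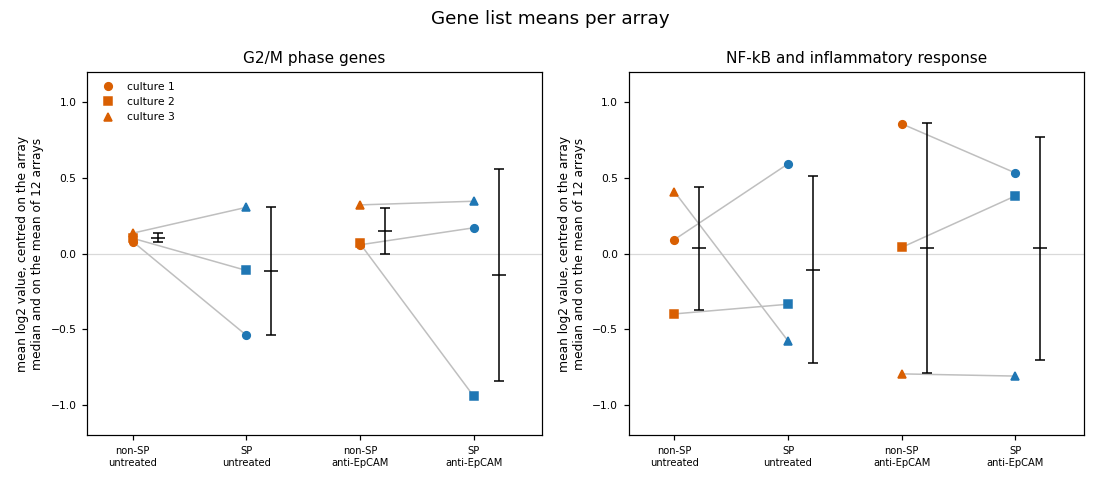
Mean log2 level of the G2/M and the NF-kB and inflammatory list on the vertical axis, centred on each array's median and on the mean of 12 arrays, with points for single arrays of the 4 groups, grey lines joining the SP and non-SP array of one culture, and bars for the mean and SD (n = 3). In the G2/M list the untreated SP arrays lie at -0.54, -0.11 and 0.31, the treated SP arrays at 0.17, -0.94 and 0.35, and the 6 non-SP arrays between 0.06 and 0.32.

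The interaction asks whether the antibody acted differently in SP and non-SP cells. Abcg2 had an interaction term of 0.02 ± 0.22 (SE), which became -0.08 after a further quantile normalization, and Epcam one of -0.03 ± 0.25 (SE). Abcb1b stood at 0.43 ± 0.60 (SE), Abcb1a at 0.17 ± 0.54 (SE) and Prom1 at -0.43 ± 0.41 (SE), and Cd44, Cd24a and Myc at -0.04, 0.00 and -0.01. With centred arrays Epcam, Cd44 and Myc turned to 0.02, 0.02 and 0.04, and after a further quantile normalization Cd24a turned to -0.02. By their other probe sets Abcb1a stood at 0.39, Abcb1b at -0.04 and Epcam at -0.24. Cd44 stood at 0.24, -0.11 and 0.29 there, and Cd24a at 0.10 and 0.21. The highest moderated t values were those of Crebl2 at 0.71, Dnajb5 at 0.61 and Zfp995 at 0.89, and the lowest those of Trim75 at -0.85, Olfr74 at -0.67 and Cacna1h at -0.70. Fcgr2b, the inhibitory antibody receptor gene, stood at -0.66 ± 0.28 (SE), in a complement and antibody receptor list that did not pass (adjusted p = 0.658). None of the named genes passed the threshold. The limma counts were 0 and 0, with 43 genes at an unadjusted p under 0.05 (7 higher, 36 lower) and 1003 with each culture as a block, where 0 passed as well. The 95% interval lay inside a 2-fold difference for 13073 genes (71.9%). No list was called (adjusted p from 0.475 to 0.999), 0 list genes passed when adjusted over the list alone, and in 4 lists the median, mean and test differed in sign. The differences in list calls between fractions and treatments described above therefore did not themselves pass a test with all arrays. Some interaction lists were called without SP untreated replicate 1, or without both arrays of treated culture 2.

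Across the 18194 genes, which are not independent replicates, the antibody's log2 changes in SP and in non-SP cells had a Pearson correlation of 0.34 and a Spearman correlation of 0.29, and 69.6% of genes had the same sign (59.5% after subtracting the median change). The SP and non-SP arrays share cultures. Regrouping whole cultures in the 9 other ways gave Pearson correlations from 0.38 to 0.81, with a median of 0.63, all above the real one. The same-sign share after subtracting the median was 62.7 to 79.8% in those regroupings. The SP minus non-SP differences in untreated and in treated cells had correlations of -0.17 and -0.16, with 45.3% of the same sign. Among genes in the upper 50% by mean level the latter Pearson correlation was 0.09. Over fits leaving out single arrays the Pearson correlation of antibody effects had an SD of 0.14. That of fraction effects had an SD of 0.16 and took either sign. Averaged over both fractions, the antibody comparison gave 0 genes past the threshold in limma, 1484 at an unadjusted p under 0.05 and a lowest adjusted p of 0.212. That fit takes the 2 arrays of a culture as independent, and on the means of the cultures 0 genes passed, 461 had an unadjusted p under 0.05 and the lowest adjusted p was 0.991. Averaged over both treatments, the fraction comparison gave 0 genes and 19 at an unadjusted p under 0.05, or 0 and 388 with each culture as a block.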

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

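Over 33 settings the 270 alternative gene counts stayed at 0 in limma, with 4 to 28, 18 to 906, 366 to 1203, 573 to 1098 and 14 to 464 genes at an unadjusted p under 0.05 when single arrays were left out, in the order of the contrasts. The highest came without SP untreated replicate 2 (28 and 1098) and without non-SP anti-EpCAM replicate 3 (906, 1203 and 464). The lowest adjusted p was 0.19, with culture as a random block. Of 1583 changes of single named genes, 25 moved by more than the residual SD, 123 took another sign and 0 passed the threshold. The settings with culture as a block and without the treated culture 2, the averages, the regrouping of whole cultures and the sign-flip tests were chosen after seeing the data. With the replicate number as a block, 2, 1, 0, 4 and 0 lists were called, as without it. The list calls did not keep. With an estimated correlation, and with fry, 0 lists were called in each contrast. The adjusted p was then 0.801 and 0.994 for the G2/M and the unfolded protein list in untreated cells, 0.891 and 0.981 for G2/M in treated cells, and 0.847 for the 4 lists of treated SP cells, with fry at 0.979 for p53 and ribosome biogenesis, 0.847 for MAPK and 0.846 for the xenobiotic list. Those 4 lists were called relative to all genes, while fry tests a change from 0. The fry values therefore cannot decide on those 4 calls. With culture as a block the treated fraction had 2 called lists, and with the estimated correlation added 0 lists, at 0.795 for both untreated lists and 0.811 for G2/M in treated cells. Array weights gave 0 lists in the treated fraction (G2/M 0.572) and 0.307 for the unfolded protein list, and the mean of probe sets gave 2 lists there. Without both arrays of treated culture 2 the treated fraction had 0 lists, with G2/M higher rather than lower at 0.131, the antibody had 4 lists in non-SP cells, the interaction had 2, p53 and ribosome biogenesis in SP cells stood at 0.256 and 0.502, and the correlation of antibody effects was 0.62. The correlation of fraction effects was 0.0887 in the upper 50% of genes. Leaving out single arrays gave 1 to 9, 0 to 5, 0 to 3, 0 to 8 and 0 to 7 called lists in that order. The 9 came without non-SP untreated replicate 2, the 5 without non-SP anti-EpCAM replicate 1, the 3 without non-SP anti-EpCAM replicate 2, and the 8 and 7 without SP untreated replicate 1. The adjusted p ranged from 1.8e-17 to 0.838 for G2/M in untreated cells (0.838 without SP untreated replicate 1) and from 1.1e-10 to 0.431 in treated cells (0.431 without non-SP anti-EpCAM replicate 3, and 0.0526 with the list higher without SP anti-EpCAM replicate 2). It ranged from 0.00081 to 0.907 for the unfolded protein list, from 0.00068 to 0.258 for MAPK, from 0.00068 to 0.637 for p53, from 0.00053 to 0.595 for ribosome biogenesis and from 0.0010 to 0.126 for the xenobiotic list. Those 4 calls ended without SP untreated replicate 2 or SP anti-EpCAM replicate 1, p53 (0.238) and ribosome biogenesis (0.595) also without SP anti-EpCAM replicate 2, and ribosome biogenesis without SP untreated replicate 3 (0.160). The correlation of antibody effects ranged from 0.16 to 0.56 and that of fraction effects from -0.38 to 0.17, positive without non-SP anti-EpCAM replicate 2 (0.17), SP anti-EpCAM replicate 1 (0.13) or SP untreated replicate 1 (0.03). For the results that did not keep, other than the G2/M calls, the cause was not tested. The number of arrays, and the low signal of many extreme genes over background, limit what these comparisons can show.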

Other observations

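The tests of cultures, RNA quality and immune markers below were chosen after their patterns had been seen, and the splits of the samples were planned, except those of whole cultures. Inflammatory genes differed widely between cultures of one treatment. The mean of the 16 NF-kB and inflammatory genes was 1.498 log2 units higher in anti-EpCAM culture 1 than in anti-EpCAM culture 3, with 14 of 16 genes higher, against an SD of 0.35 between the 2 arrays of a culture. These cultures were picked as the highest and lowest in this mean, so that count is no separate support. With centred arrays the SP minus non-SP difference of the list was 0.50, 0.06 and -0.99 in the untreated cultures. In the treated cultures it was -0.32, 0.34 and -0.01. After centring each array, Il6, an inflammatory cytokine gene, was 3.02 higher, Icam1, an adhesion receptor gene, 3.38 higher and Lcn2, an iron-binding defence protein gene, 3.69 higher.

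Different RNA quality is a possible explanation for that pattern, but the actin 3' minus 5' signal, a measure of RNA breakdown, differed by 0.003 between these cultures (SD 0.11 between arrays of a culture). Immune cells in the culture stay open. The mean of 11 immune markers differed by -0.0936 (SD 0.11), with 5 of 11 higher, but that mean rests on the T cell gene Cd3e at -1.18, and the other 10 averaged 0.015. Csf1r, the most abundant of them at a mean of 9.98, was 0.80 higher and Cd68 0.28 higher. Fcgr3 differed by -0.49, Ptprc by -0.30, Fcer1g by -0.28, and Laptm5 and Itgam by -0.14 each. Ptprc and Itgam had low mean levels, at 3.42 and 3.87, so their differences say little. Over the 6 cultures the NF-kB list had a Pearson r of 0.10 with actin (exact permutation p = 0.839, Spearman rho -0.09 with p = 0.919) and of 0.15 with the immune markers (exact p = 0.774, rho 0.03 with p = 1), adjusted to 0.839 and 1 in a family of 3 relations. Without the 2 farthest cultures r was -0.34 and 0.76. No explanation other than RNA quality and immune cells was tested.

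In treated cells culture 2 supplied the lower G2/M genes of SP arrays, as given above. Whether single cultures carry the difference over all 6 cultures stays open. The exact sign-flip p over 6 cultures was 0.281, where the smallest possible is 0.0312, which cannot separate this from a shared difference. Untreated cultures 1 and 2 stood at -0.66 and -0.25 and anti-EpCAM culture 2 at -0.91, and the others at 0.17, 0.20 and -0.001. Unequal RNA quality of the paired arrays stays open, with a Pearson r of 0.11 between the list difference and the actin difference (exact permutation p = 0.835, adjusted 0.839, Spearman rho -0.03 with p = 1, and r -0.44 without the 2 farthest cultures). In untreated culture 1, at -0.66, the actin signal was 0.209 in both arrays. In untreated culture 3, at 0.17, it was 0.404 in the non-SP and 0.733 in the SP array. Anti-EpCAM culture 2, at -0.91, had 0.895 in the non-SP and 1.03 in the SP array. Unequal actin signals thus do not go with the difference in untreated culture 1. Over all 6 cultures RNA quality and a difference between the fractions cannot be told apart. A difference in cycling between the fractions stays open, and it was looked at only through these transcripts.

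The 2 arrays of anti-EpCAM culture 2 correlated least with the others, at a mean of 0.982 and 0.985 against 0.987 to 0.990 for the other 10. Degraded RNA is a candidate explanation, since their actin 3' minus 5' signals were 0.895 and 1.03 against at most 0.733 elsewhere, and their Gapdh signals 0.456 and 0.497 against at most 0.231.

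For each of the first 4 contrasts there are 10 splits of the 6 arrays into 3 and 3, so the share is never under 0.1. In untreated cells 9 of 10 splits gave at least the real 4 genes at an unadjusted p under 0.05 (highest other 1869) and 9 at least the real 2 lists (highest other 8). In treated cells 8 gave at least the real 127 genes (highest other 3460) and 9 at least the real 1 list (highest other 7). For the antibody in non-SP cells 5 splits gave at least the real 585 genes (highest other 1817) and 10 at least 0 lists, as any split does (highest other 9). In SP cells 5 gave at least the real 835 genes (highest other 1290) and 4 at least the real 4 lists (highest other 11). Of the 100 splits drawn for the interaction, 97 gave at least the real 43 genes (highest other 4595) and 100 at least 0 lists (highest other 11). Those splits mix arrays of one culture, and a count of 0 is reached by any split, so neither decides anything. With whole cultures regrouped and culture as a block, 5 of 10 splits gave at least the real 1003 genes (highest other 3974), and the share is again never under 0.1. The high counts of other splits point to a structure of the samples. Among the 4 splits that part all 3 cultures, the highest other counts were 11 genes in untreated and 806 in treated cells, while splits keeping a culture together gave 611 to 1869 and 1142 to 3460.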
